A study of Homo sapiens with 18 samples.

How the data were processed

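The series measured RNA from HepG2 cells, an established human hepatocellular carcinoma line, on 18 single-colour Affymetrix Human Gene ST arrays. Per the labels, cell clones carrying an expression plasmid for thyroid hormone receptor TRα1 (6 clones pooled), TRβ1 (12 clones pooled) or the empty plasmid (11 clones pooled) were combined into 1 pool per construct. Each pool received 100 nM T3 (triiodothyronine, the active thyroid hormone) or the ethanol vehicle for 6 h in medium with 10% hormone-stripped serum, and 3 independent biological repeats were taken per group. From each, 200 ng of total RNA was amplified and labelled.

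The deposited values are log2 expression per transcript cluster after RMA (background correction, quantile normalization and median polish), which the authors ran in R 2.7.1 per the submitters' processing notes. The table held 32321 features by 18 arrays, with values between 0.894 and 13.7 and array medians between 5.31 and 5.49. A gene symbol was available for 20546 features, of which 19158 carried a single gene and 1388 several. These stood for 18404 genes, 637 of them with more than 1 feature. The 11775 features without a symbol were left out of the main tests and counted separately. No genome build was given with the table, so no coordinates are reported. Arrays have no read depth, and their number, 3 per group, limits the precision. The median standard error of a difference between groups was 0.157 on the log2 scale.

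A linear model with the 6 groups was fitted to every tested feature with limma 3.58.1 in R 4.3.3, followed by its empirical Bayes moderated test. Each feature shared 1 residual variance over the 18 arrays. There were 9 contrasts: T3 against vehicle in each pool, the 3 differences between these responses, and the 3 differences between pools on vehicle. P-values are two-sided and adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Counts of features with an unadjusted p under 0.05 are printed beside some results. Each count printed with a result was below the share of 0.05 of the 20546 features that chance alone gives on average. These counts are no sign of further changes, nor of their absence. With the replicate number as a block (next paragraph), the counts were 1396, 1270 and 1222 for T3 in the TRα1, TRβ1 and control pools. On vehicle they were 2789, 2220 and 1584 for TRα1 against control, TRβ1 against control and TRβ1 against TRα1. All of these lay above that share. Differences are log2 values, T3 minus vehicle or the first named pool minus the other, with the standard error (SE) of the model. Group levels are means with the standard deviation (SD).

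Whether arrays with the same replicate number belonged together was checked on the values after subtracting group means. All 45 pairs of arrays that shared a number but not a group correlated positively across features, the lowest at 0.259. Pairs with different numbers had a median of -0.483 and reached 0.455. For 18 of 18 arrays, the best correlated array of another group had the same number. The numbers were therefore read as pairing the arrays. The fit fixed in advance had no such term. The fit with the replicate number as a block is given beside a result where it moves a count over all features by more than 1.5 times. Calls of gene list members are those without the block unless the block is named, and further members passed with it. With the block the median standard error was 0.107.

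The genes named in each contrast were up to 12 higher and 12 lower genes with the largest change among features with a single gene, an adjusted p under the threshold and no overlap between the values of both groups, a separation that chance gives to 10% of features at 3 arrays against 3. For a gene with several features, the one with the highest mean was used. THRA and THRB were always named, and up to 4 members of each gene list. Genes taken from the fit with the block, and others said to be so, were chosen after their values were seen.

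Gene lists for hormone action, liver metabolism, signalling, stress and cell type markers, 36 in all, held 620 entries, of which 563 matched a tested feature and 4 of those through a synonym. The other genes were not analysed here. Lists were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, and again with an estimated correlation. The limma function fry served as a second method. Features called in 1 pool were also tested with camera in contrasts that share no arrays with the calls. Overlaps were compared with a one-sided Fisher's exact test across features, and features are not independent. Because the comparisons with control use the same control arrays, the features they shared were also measured on the T3 arrays, and the covariance of both comparisons was set against arrays simulated without any group difference.

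The groups, contrasts, threshold, gene lists, rule for named genes and most alternative settings were set before the data were examined. The alternatives were the replicate block as a fixed or random term, only the arrays of the groups compared, renewed quantile normalization, centring on array medians, omission of dim features, inclusion of all features, 1 feature per gene, a trended and robust variance prior, array weights, a minimum change of 1.5-fold, and each array left out in turn. The tests were tried on simulated arrays with 20546 features, 50 of them changed at each size. For T3 against vehicle in 1 pool, the fit without the block recovered 72% of changes of 1 log2 unit and 8% of changes of 0.5, with 0 false calls. With the block it recovered 96% and 64%, with 7 false calls. For the difference between 2 responses, the recovery at 1 log2 unit was 24% without and 86% with the block. Camera called the shifted list, 1 of 36, and no other. Simulated features were drawn independently, so this could not show how camera behaves with correlated genes. The simulated arrays held the replicate effects and residual spread of the fit with the block, which favours that fit.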

Results

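Expression was measured in 6 groups of 3 arrays: HepG2 pools carrying TRα1, TRβ1 or the empty plasmid (control), each on ethanol vehicle or on 100 nM T3 for 6 h. The series title asks which targets the 2 receptor isoforms share and how their activity differs. The array medians lay between 5.31 and 5.49 on the log2 scale. The largest difference between arrays followed the replicate number and not the groups: component 1 held 49.2% of the variance and placed the 6 arrays numbered 1 between -39.2 and -32.3, those numbered 2 between 11.99 and 20.4, and those numbered 3 between 14.3 and 22.6. Component 2 held 10.9%.

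**Figure D1:**
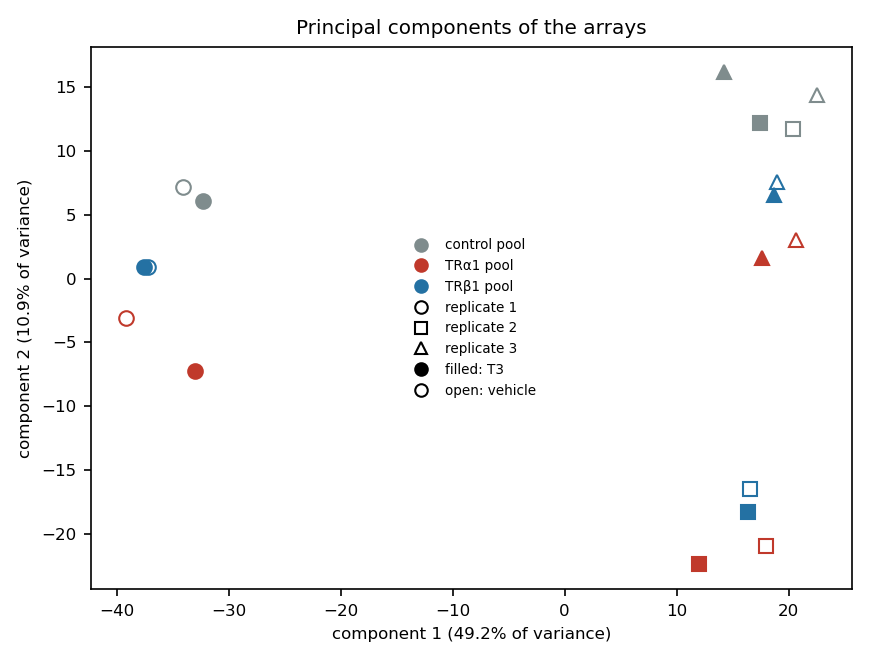
Each point is 1 array, placed by its scores on principal components 1 (49.2% of variance, horizontal) and 2 (10.9%, vertical), with colour for the pool, shape for the replicate number and filled symbols for T3. The 6 arrays of replicate number 1 lie between -39.2 and -32.3 on component 1, and the other 12 between 11.99 and 22.6.

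THRA, the gene for TRα (feature 8007008), stood at 7.50 ± 0.10 (SD, n = 3) on vehicle and 7.96 ± 0.26 on T3 in the TRα1 pool. In the control pool it stood at 7.06 ± 0.12 and 7.01 ± 0.21, and in the TRβ1 pool at 7.07 ± 0.15 and 7.01 ± 0.16. The vehicle difference between the TRα1 and control pools was 0.44 ± 0.14 (SE), higher in 3 of 3 same-numbered pairs, with an adjusted p of 0.533 without and 0.128 with the block. THRB, the gene for TRβ (feature 8085797), stood at 6.95 ± 0.07 on vehicle in the TRβ1 pool and 6.65 ± 0.24 in the control pool, a difference of 0.30 ± 0.15 with an adjusted p of 1. On T3, THRB differed from vehicle by 0.45 ± 0.15, 0.47 ± 0.15 and 0.43 ± 0.15 in the TRα1, TRβ1 and control pools, higher in 3 of 3 pairs of each, and none passed the threshold over all features. Which parts of the plasmid-encoded transcripts the probes cover is unknown, so these levels do not measure the introduced receptors.

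The comparison of T3 with vehicle in the TRα1 pool asks which genes responded to hormone where TRα1 was added. CYP24A1, the enzyme that degrades active vitamin D, rose by 1.86 ± 0.30 (SE, n = 3 per group) on the log2 scale, a 3.62-fold change, COQ10A, a coenzyme Q binding protein, by 1.85 ± 0.15, and FYN, a Src family kinase, by 1.79 ± 0.13. SCNN1A, a subunit of the epithelial sodium channel, rose by 1.77 ± 0.24, HEG1 by 1.64 ± 0.17, TP53INP2, an autophagy protein, by 1.62 ± 0.25 and TNS4, a tensin of cell adhesions, by 1.48 ± 0.20. KCNJ10, a potassium channel, rose by 1.45 ± 0.15, ENG, a TGF-β coreceptor, by 1.35 ± 0.17, PTAFR, the receptor for platelet-activating factor, by 1.35 ± 0.16, the zinc finger protein HIVEP2 by 1.22 ± 0.12 and MPV17L by 1.10 ± 0.16. SLC2A1, the glucose transporter GLUT1, was the single gene that fell, at -0.57 ± 0.10 (adjusted p = 0.019). For every gene named here the 3 values on T3 lay beyond the 3 on vehicle. In limma, 27 of 20546 features passed, 26 higher and 1 lower, where adjusted p ranged for the genes named here from 9.6e-06 for FYN to 0.019 for SLC2A1. With the replicate block 137 features passed, 120 higher and 17 lower, among them all 27. Among the genes ranked in that fit, and chosen after their values were seen, were the gluconeogenic enzyme G6PC1 at 1.35 ± 0.17 (SE with the block), the glycogen branching enzyme GBE1 at 1.33 ± 0.13 and the hyaluronan-degrading protein CEMIP at -0.74 ± 0.10, none of which passed without it. With only the arrays of this pool, 6 features passed.

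Of 36 gene lists, 4 passed camera at the preset correlation in the TRα1 pool, and none did with an estimated one. Textbook thyroid hormone responsive genes were higher as a group, with a median of 0.14 over 25 genes (adjusted p = 3.6e-08; adjusted p = 0.133 with an estimated correlation). Among them CPT1A, which carries fatty acids into mitochondria, rose by 1.09 ± 0.19 and SLC2A1 fell, and the other 23 did not pass over all features. Adjusted over the list alone, 5 rose and 1 fell, the former including G6PC1, the gluconeogenic enzyme PCK1 (1.02 ± 0.28), the transcription factor KLF9 (0.54 ± 0.14) and THRB. With the block this list had an adjusted p of 2.9e-08, and an adjusted p = 0.011 with an estimated correlation. G6PC1, PCK1 (adjusted p = 0.014) and KLF9 (adjusted p = 0.027) then also passed over all features in limma. Acute phase and complement genes were higher (median 0.16 over 18 genes, adjusted p = 0.012; adjusted p = 0.343 with an estimated correlation), with 0 members called over all features and 2 adjusted over the list alone, MASP1 at 0.62 ± 0.14 and FGA at 0.34 ± 0.10. With the block MASP1 passed over all features in limma (adjusted p = 0.011), and FGA did not (adjusted p = 0.070). Bile acid and nuclear receptor targets were higher (adjusted p = 0.033; adjusted p = 0.133 with an estimated correlation), with 0 members called over all features and 1 adjusted over the list alone, the phospholipid exporter ABCB4 at 0.66 ± 0.14. With the block ABCB4 (adjusted p = 0.024) and SLC51B (0.83, adjusted p = 1.2e-04) passed over all features in limma. Wnt target genes were lower (median -0.09, adjusted p = 0.047; adjusted p = 0.780 with an estimated correlation) with 0 members called either way, and the members with the largest values, APCDD1 at -0.40 ± 0.12 and DKK1 at -0.41 ± 0.14, are known as inhibitors of Wnt signalling. With the block 9 lists passed, the added ones being xenobiotic metabolism, apolipoproteins, coagulation, circadian genes, and cell cycle inhibitors and p53 targets, and with the block and an estimated correlation 1 did, the textbook list. Of single members of other lists, the circadian repressor NR1D1 rose by 0.52 ± 0.09, the interferon regulator IRF1 by 1.09 ± 0.17 and CD14, a monocyte marker and lipopolysaccharide coreceptor, by 0.90 ± 0.15.

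T3 against vehicle in the TRβ1 pool asks the same of TRβ1. CYP24A1 rose by 1.83 ± 0.30 (SE, n = 3 per group), HEG1 by 1.73 ± 0.17, COQ10A by 1.67 ± 0.15 and PCK1 by 1.63 ± 0.28. TP53INP2 rose by 1.55 ± 0.25, FYN by 1.40 ± 0.13, HIVEP2 by 1.26 ± 0.12, SERPINB9, an inhibitor of granzyme B, by 1.06 ± 0.17 and PTAFR by 0.99 ± 0.16. TTC39C rose by 0.94 ± 0.11, while its other feature differed by 0.30 and did not pass, and RASSF4 and GPCPD1 each rose by 0.79 ± 0.13. SLC2A1 fell, at -0.65 ± 0.10, again the single lower gene. The 3 values on T3 lay beyond the 3 on vehicle for each of these. In limma 15 features passed, 14 higher and 1 lower, with adjusted p from 1.0e-04 for COQ10A, FYN and HIVEP2 to 0.042 for NR1D1 and PCK1, the latter of which did not pass with array weights (adjusted p = 0.106). With the block 98 passed, 83 higher and 15 lower, among them all 15. Genes ranked in that fit, chosen after their values were seen, included the kinase SGK1 at 1.01 ± 0.11 (SE with the block), CPT1A at 0.98 ± 0.10 and ANKRD1 at -0.81 ± 0.13, none of which passed without it. With only the arrays of this pool 0 features passed in limma (457 had an unadjusted p under 0.05 in the fit to all arrays), and 4 passed with the arrays numbered 2 and 3 alone, a setting added after the data were seen.

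In the TRβ1 pool 7 lists passed camera, and none did with an estimated correlation. Textbook thyroid hormone responsive genes were higher (median 0.11, adjusted p = 1.1e-08; adjusted p = 0.111 with an estimated correlation), where PCK1 rose and SLC2A1 fell over all features, and 6 rose and 1 fell adjusted over the list alone. Acute phase and complement genes were higher (median 0.15, adjusted p = 2.8e-04; adjusted p = 0.142 with an estimated correlation), with 0 members called over all features and 2 adjusted over the list alone, MASP1 at 0.76 ± 0.14 and FGA at 0.46 ± 0.10. Xenobiotic metabolism was higher (median 0.11, adjusted p = 0.0039; adjusted p = 0.077 with an estimated correlation) with 0 members called either way, CYP3A5 standing at 0.49 ± 0.21. With the block these 3 lists also passed with an estimated correlation, at adjusted p = 0.012, 0.018 and 0.018. Among their members, limma with the block called G6PC1 (adjusted p = 0.022), MASP1 (0.0033), FGA (0.011), HAMP (0.0049) and CYP3A5 (0.041) over all features. Circadian genes were higher (adjusted p = 0.012; adjusted p = 0.385 with an estimated correlation), where NR1D1 rose by 0.53 ± 0.09, and 2 members, NR1D1 and DBP (0.38 ± 0.11), passed adjusted over the list alone. Coagulation and fibrinolysis genes were higher (adjusted p = 0.018; adjusted p = 0.402 with an estimated correlation), with 0 members called over all features and 2 adjusted over the list alone, F13B at 0.84 ± 0.25 and FGA. Inflammatory cytokines and NF-kB targets were higher (adjusted p = 0.021; adjusted p = 0.225 with an estimated correlation) and growth factor and insulin signalling genes lower (adjusted p = 0.040; adjusted p = 0.807 with an estimated correlation), each with 0 members called either way. The largest values among them were 0.39 ± 0.12 for BCL3 and -0.50 ± 0.36 for IGFBP1. With the block IGFBP1 passed over all features in limma (adjusted p = 0.045). With the block 8 lists passed, the added one being lipogenesis (adjusted p = 0.037; adjusted p = 0.271 with the block and an estimated correlation).

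The control pool shows what T3 did without added receptor. HEG1 rose by 1.56 ± 0.17 (SE, n = 3 per group) and COQ10A by 1.39 ± 0.15, each with an adjusted p of 0.0013 and all 3 values on T3 above the 3 on vehicle. In limma these were the 2 features that passed. With the block 20 passed (3 to 9 with any single control array left out), all higher, including TP53INP2 at 1.18 ± 0.12 (SE with the block), the coagulation factor subunit F13B at 1.10 ± 0.19, SCNN1A at 0.84 ± 0.13 and FYN at 0.64 ± 0.10, chosen after their values were seen. Coagulation and fibrinolysis was the single list that passed (median 0.04, adjusted p = 0.048; adjusted p = 0.907 with an estimated correlation), with 0 members called over all features and 1, F13B, adjusted over the list alone. With the block 5 lists passed, coagulation, acute phase, xenobiotic metabolism, circadian genes and apolipoproteins, and 0 with the block and an estimated correlation. With only the arrays of this pool, 0 features passed in limma, and 417 had an unadjusted p under 0.05 in the fit to all arrays.

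**Figure D2:**
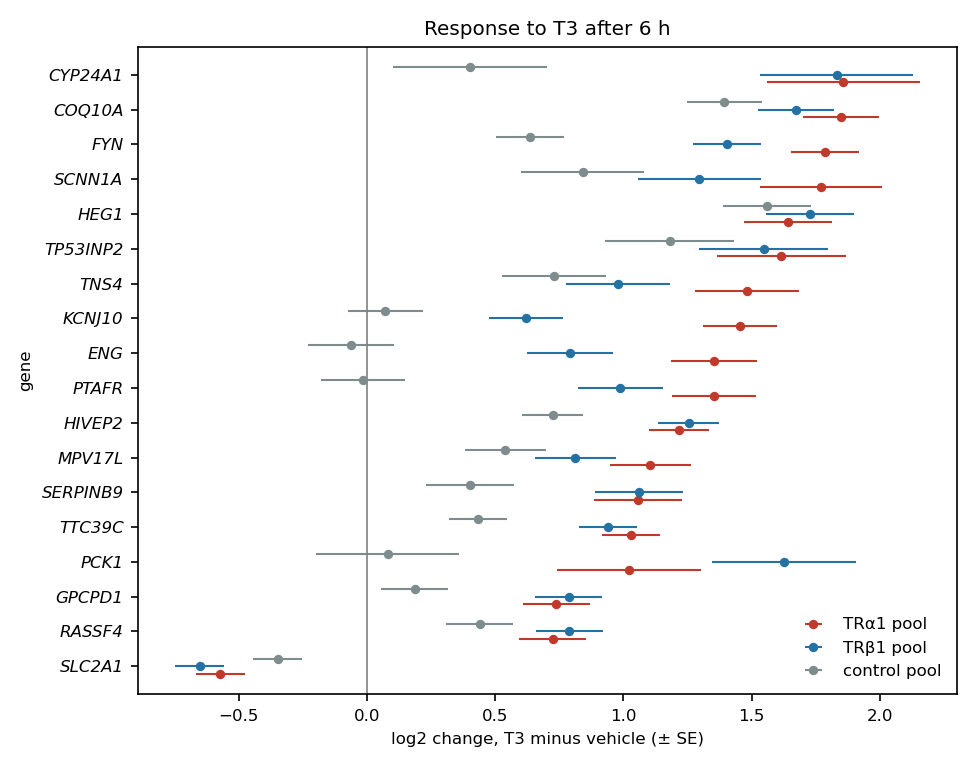
Log2 change with T3 (T3 minus vehicle, horizontal) of genes named in the comparisons of T3 with vehicle, in the TRα1, TRβ1 and control pools, as model estimates ± SE from 3 arrays per group. HEG1 lies at 1.64, 1.73 and 1.56 in the 3 pools, and KCNJ10 at 1.45, 0.62 and 0.07.

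The responses of both receptor pools overlapped. Of the 26 features higher in the TRα1 pool and the 14 higher in the TRβ1 pool, 13 were the same, against 0.0177 for independent draws (one-sided Fisher's exact p = 7.8e-39 across features), and SLC2A1 was the lower gene of both. With single arrays of these pools left out, this overlap of 14 fell to between 5 and 12, and the TRβ1 count of 15 to between 5 and 10. The shared genes included CYP24A1, COQ10A, FYN, HEG1, TP53INP2, PTAFR, HIVEP2, SERPINB9 and NR1D1, and 0 features were called in opposite directions. With the block 76 of 120 and 83 higher features and 9 of 17 and 15 lower ones were shared. Of the 20 features called in the control pool with the block, a count that fell to 3 to 9 with any single control array left out, 19 were also higher in the TRα1 pool and 18 in the TRβ1 pool. Over all 20546 features, which are not independent replicates, the responses correlated at 0.318 between both receptor pools, 0.259 between the TRα1 and control pools and 0.175 between the TRβ1 and control pools. The 26 features called higher in the TRα1 pool had a median of 0.44 in the control pool, above 0 for 24 (camera p = 1.1e-55; p = 2.3e-06 with an estimated correlation), and the 14 called higher in the TRβ1 pool a median of 0.42, above 0 for 13 (p = 2.7e-39; p = 1.6e-06 with an estimated correlation). On vehicle the same 26 had a median of -0.01 in the TRβ1 minus control difference (p = 0.228; p = 0.534 with an estimated correlation). The features called higher in the TRβ1 pool had a median of -0.01 in the TRα1 minus control difference on vehicle, and camera, whose direction was up, did not call them (p = 0.363 across genes; p = 0.558 with an estimated correlation).

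**Figure D3:**
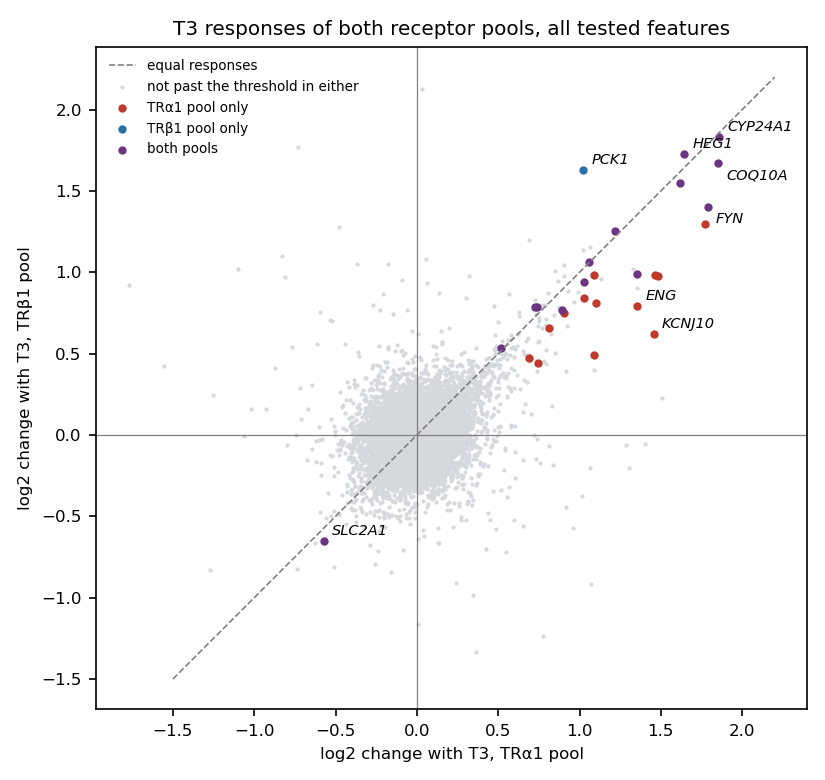
Each point is a tested feature, placed by its log2 change with T3 in the TRα1 pool (horizontal) and in the TRβ1 pool (vertical), coloured by the pools in which it passed the threshold, with a dashed line at equal responses. CYP24A1 lies near the line at 1.86 and 1.83, and KCNJ10 lies below it at 1.45 and 0.62.

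Whether the response to T3 differed in a receptor pool was tested by the difference from the response of the control pool. With 1 pool of clones per construct, receptor and clones cannot be told apart here. For the TRα1 pool the differences were 1.41 ± 0.24 for ENG, 1.38 ± 0.21 for KCNJ10, 1.37 ± 0.23 for PTAFR and 1.15 ± 0.19 for FYN, with adjusted p of 0.130, 0.109, 0.130 and 0.130, and in the control pool ENG, KCNJ10 and PTAFR had responses of -0.06, 0.07 and -0.01. In limma 0 features passed without the block, and 286 had an unadjusted p under 0.05, fewer than chance alone gives. That count does not show equal responses. With the block 6 passed, all higher: these 4 genes, CYP24A1 at 1.46 ± 0.21 (SE with the block, adjusted p = 0.015) and the zinc finger gene ZNF717 at 1.01 ± 0.11 (adjusted p = 0.0041). The response of ZNF717 was 0.66 in the TRα1 pool and -0.34 in the control pool, so part of its difference lay in the control pool. For the TRβ1 pool 0 features passed in limma in either fit (unadjusted p under 0.05 for 275 without and 835 with the block), with PCK1 at 1.55 ± 0.40, CYP24A1 at 1.43 ± 0.42 and PTAFR at 1.003 ± 0.23. Genes of these differences were chosen after their values were seen. CYP24A1 rose from a lower level on vehicle than in the control pool, at -1.04 in the TRα1 pool and -1.68 in the TRβ1 pool. In the TRβ1 pool this gap was larger than the difference of responses, so its mean on T3 stayed below that of the control pool. Textbook thyroid hormone responsive genes responded more than in the control pool with TRα1 (median difference 0.10, adjusted p = 0.0057; adjusted p = 0.631 with an estimated correlation) and with TRβ1 (median 0.10, adjusted p = 0.011; adjusted p = 0.981 with an estimated correlation). No member passed over all features, and adjusted over the list alone 0 passed with TRα1 and 1, PCK1, with TRβ1. The other 35 lists did not pass in either difference.

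The difference between the responses of the TRβ1 and TRα1 pools addresses isoform-specific activity. Each construct had 1 pool of clones and the introduced receptors were not measured, so isoform, clones and receptor amount cannot be told apart. Over all features 0 passed in limma in either fit, and 0 of 36 lists passed camera. An unadjusted p under 0.05 was reached by 223 features without and 619 with the block, fewer than chance alone gives. These counts do not show equal responses. On simulated arrays, 24% of such differences of 1 log2 unit were recovered without the block and 86% with it. Among the 28 features called in either pool, 14 were called in both, and the estimates of all 28 had the same sign in both; 27 of them were called in the TRα1 pool, a choice that favours larger changes there. KCNJ10 responded less in the TRβ1 pool, at 0.62 against 1.45, a difference of -0.83 ± 0.21 (95% interval -1.27 to -0.40, adjusted p = 0.027 over the 28 features). IRF1 differed by -0.59 (interval -1.11 to -0.08) and ENG by -0.56 (interval -1.06 to -0.06), each with an adjusted p of 0.295, and PCK1 by 0.60 (interval -0.24 to 1.45). CYP24A1 differed by -0.03 with an interval of -0.92 to 0.87, and HEG1 by 0.08 with an interval of -0.43 to 0.60, so that sizeable differences were not excluded. With the block the intervals were narrower, at -0.47 to 0.42 for CYP24A1 and -0.26 to 0.43 for HEG1. Those of IRF1, ENG and PCK1 were then -0.98 to -0.21, -0.96 to -0.16 and 0.04 to 1.17. These genes did not pass over the features called with the block. With the block 150 features were called in either pool, 148 with the same sign in both, and 4 differed over these: KCNJ10, EXOC5 at -0.70 ± 0.13 (0.13 in the TRα1 pool, adjusted p = 0.940, and -0.57 in the TRβ1 pool), ETNPPL at -0.69 ± 0.16 and ZNF717 at -0.47 ± 0.11, the last 3 chosen after their values were seen. Without the block, the count of 1 ranged from 0 to 3 when single arrays were left out.

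**Figure D4:**
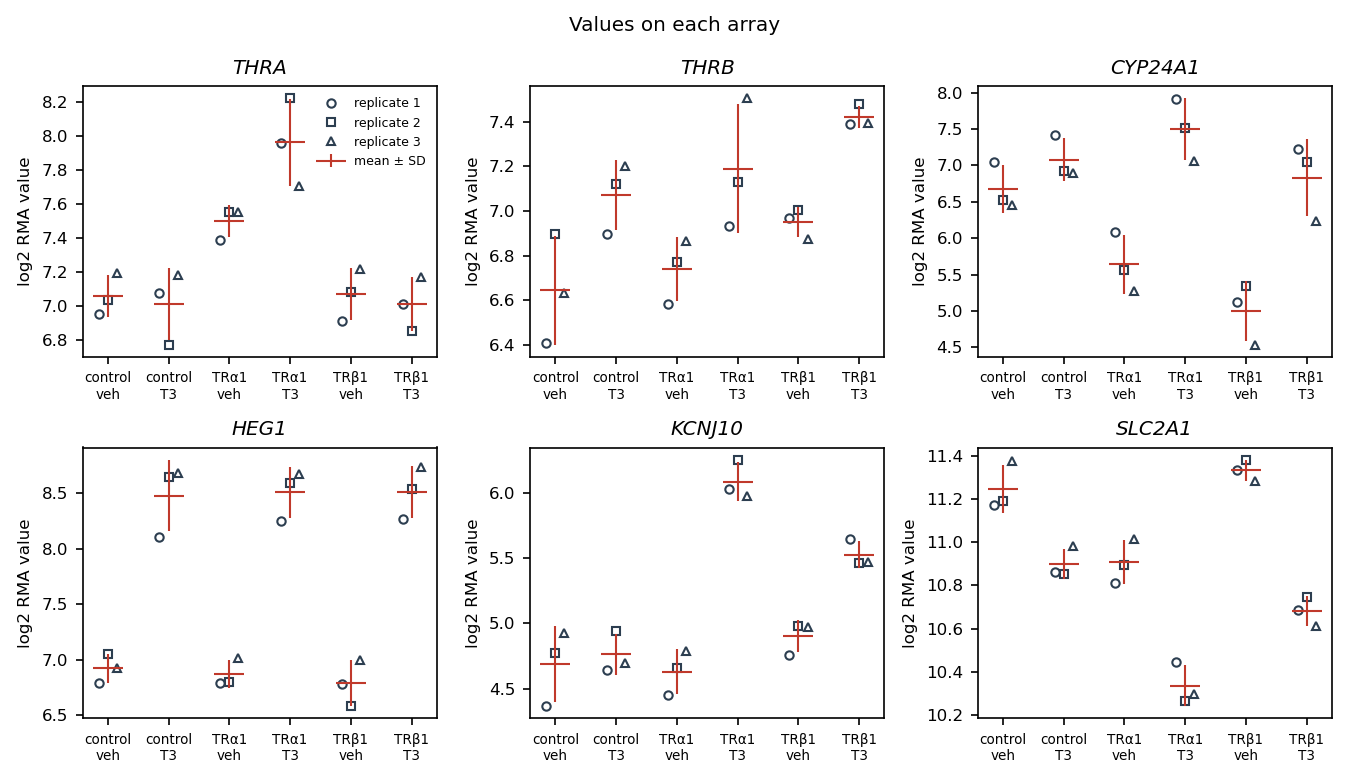
Log2 RMA values (vertical) of THRA, THRB, CYP24A1, HEG1, KCNJ10 and SLC2A1 on each array, by pool and treatment, with symbols for the replicate number and lines for the mean ± SD of 3 arrays. CYP24A1 has a mean of 6.68 on vehicle in the control pool, 5.64 in the TRα1 pool and 5.00 in the TRβ1 pool.

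On vehicle, the TRα1 pool was compared with the control pool to see how the pools differed before hormone. VCAN, a matrix proteoglycan, was higher by 2.47 ± 0.22 (SE, n = 3 per group), a 5.53-fold difference, CHN1 by 1.97 ± 0.16, UGT2B4, a glucuronosyltransferase of bile acids and steroids, by 1.86 ± 0.17 and ENPP2, the secreted enzyme autotaxin, by 1.84 ± 0.15. OLFML1 was higher by 1.74 ± 0.20, SULT1C2 by 1.66 ± 0.24, the tight junction protein CLDN6 by 1.60 ± 0.32, CYBRD1, a ferric reductase, by 1.46 ± 0.14, ARSI by 1.44 ± 0.26 and SLAIN1 by 1.43 ± 0.18. The histone genes H2BC12 (2.72 ± 0.53) and H2AC12 (1.81 ± 0.21) were also higher, with the limit that histone paralogs are close in sequence. PROM1, a progenitor marker, was lower at -1.87 ± 0.17, BICC1 at -1.48 ± 0.22, DOCK9 at -1.45 ± 0.25, ANKRD1 at -1.06 ± 0.17, GDA at -0.97 ± 0.19, PTGR1 at -0.90 ± 0.13 and DPYD, which degrades pyrimidines, at -0.75 ± 0.13. ZNF558 (-0.69 ± 0.13), GPC3 (-0.64 ± 0.12), NR0B2, the bile acid-induced repressor SHP (-0.63 ± 0.11), VPS54 (-0.59 ± 0.11) and HDAC1 (-0.54 ± 0.10) were lower too. FYN, chosen after its values were seen, was higher by 0.86 ± 0.13 (adjusted p = 0.0072). All 3 values of each named gene lay on 1 side of the 3 control values. In limma 63 features passed, 50 higher and 13 lower, with adjusted p for the named genes between 1.5e-05 for CHN1 and ENPP2 and 0.047 for CLDN6. With the block 425 passed, 284 higher and 141 lower, and with only the arrays of both groups 13 passed. H2BC12 and CLDN6 no longer passed with renewed quantile normalization or median centring, nor ZNF558 and GPC3 with the former.

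Wnt target genes were higher in the TRα1 pool on vehicle (median 0.22, adjusted p = 0.0019; adjusted p = 0.704 with an estimated correlation), the single list called. APCDD1, a target gene that encodes a Wnt inhibitor, was higher by 0.97 ± 0.12 (adjusted p = 0.0012), the other 14 members did not pass over all features, and 2 passed adjusted over the list alone, APCDD1 and the glutamine synthetase gene GLUL (0.35 ± 0.11). With the block cholesterol biosynthesis and uptake passed too (adjusted p = 6.2e-04; 0.053 without the block; adjusted p = 0.304 with the block and an estimated correlation). Of single members of other lists, MX2, an interferon-induced GTPase, was higher by 0.66 ± 0.10, BHMT, an enzyme of methionine metabolism, by 0.98 ± 0.20 and ITIH4, a secreted liver protein, by 0.62 ± 0.10.

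The TRβ1 pool differed from the control pool on vehicle in many of the same genes. VCAN was higher by 1.83 ± 0.22 (SE, n = 3 per group), UGT2B4 by 1.31 ± 0.17, OLFML1 by 1.30 ± 0.20, KLHL13 by 1.19 ± 0.15, CHN1 by 1.15 ± 0.16, H2AC12 by 1.15 ± 0.21 and the protein kinase C gene PRKCH by 1.09 ± 0.12. HEPACAM (1.05 ± 0.16), CPED1 (1.02 ± 0.10), SLAIN1 (1.01 ± 0.18), ENPP2 (0.98 ± 0.15) and MUC15 (0.93 ± 0.17) were higher as well. CYP24A1 was lower at -1.68 ± 0.30, with means of 5.00 ± 0.41 (SD) against 6.68 ± 0.33, BICC1 at -1.33 ± 0.22, PTGR1 at -1.08 ± 0.13, PROM1 at -1.05 ± 0.17, CDCA7L at -0.94 ± 0.16 and the Wnt inhibitor DKK1 at -0.78 ± 0.14. Each was separated from the 3 control values on all 3 arrays. In limma 24 features passed, 18 higher and 6 lower, with adjusted p for the named genes between 3.0e-04 for CPED1 and 0.044 for SLAIN1. With the block 151 passed, 104 higher and 47 lower, and CYP24A1 was then also lower in the TRα1 pool (-1.04 ± 0.15, SE with the block, adjusted p = 0.0012; 0.343 without). With only the arrays of both groups 0 passed in limma, where 722 had an unadjusted p under 0.05 in the fit to all arrays. CYP24A1, H2AC12, SLAIN1, MUC15 and CDCA7L no longer passed with renewed quantile normalization or median centring.

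Of the lists, cholesterol biosynthesis and uptake was higher in the TRβ1 pool on vehicle (median 0.14, adjusted p = 9.8e-04; adjusted p = 0.245 with an estimated correlation) with 0 of 18 members called over all features or adjusted over the list alone, LSS standing at 0.48 ± 0.28 and MVK at 0.36 ± 0.13. Interferon response genes were higher (median 0.12, adjusted p = 0.0054; adjusted p = 0.077 with an estimated correlation), where MX2 was higher by 0.70 ± 0.10 (adjusted p = 0.0093), the other 16 did not pass, and adjusted over the list alone MX2 and MX1 (0.56 ± 0.12) passed. Both comparisons with control shared 17 called features, 14 higher and 3 lower, and 96 with the block. As both used the same 3 control arrays, the 17 were also measured on the T3 arrays, where all 17 differed from control in the same direction in both pools.

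**Figure D5:**
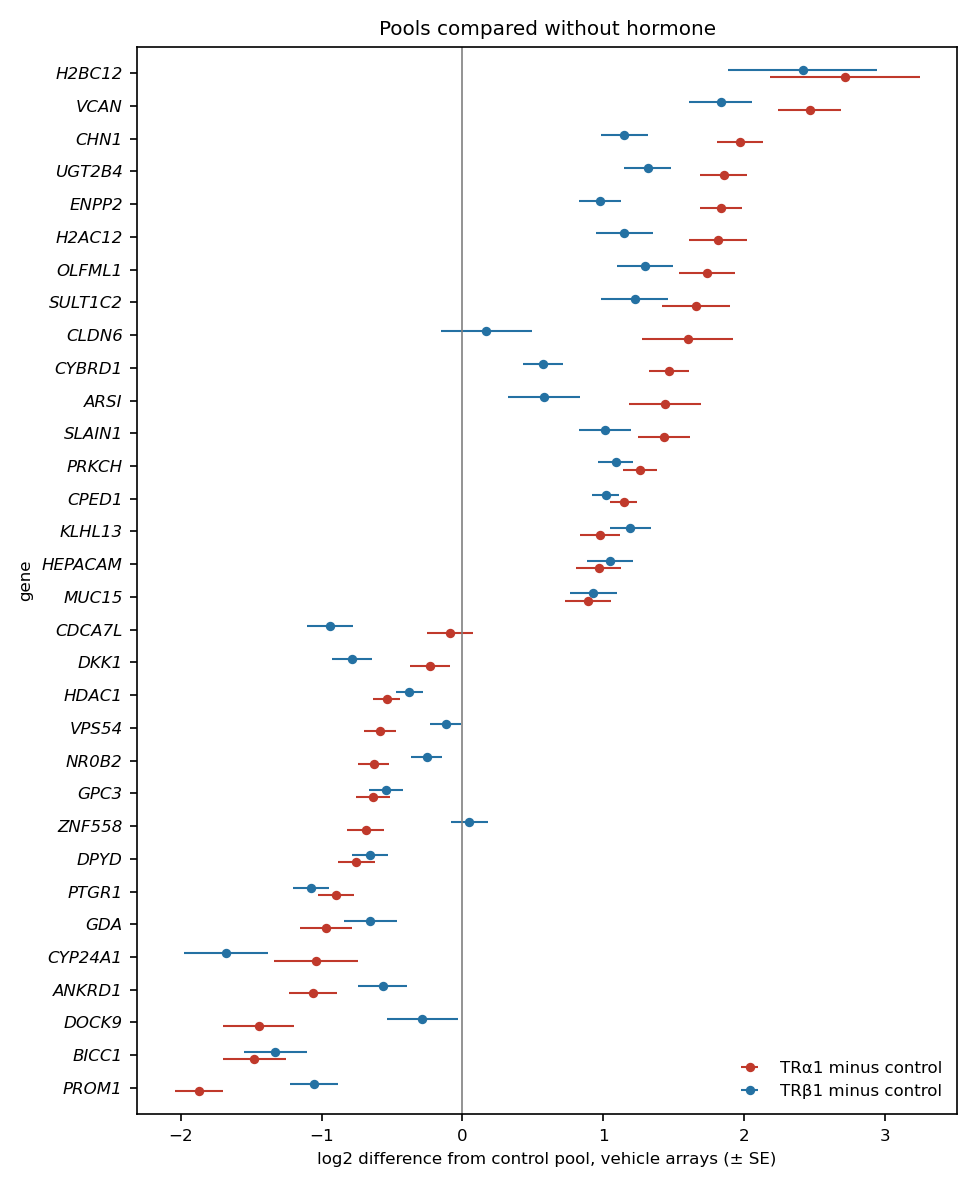
Log2 difference from the control pool on vehicle (horizontal) of genes named in those comparisons, for the TRα1 and TRβ1 pools, as model estimates ± SE from 3 arrays per group. VCAN lies at 2.47 and 1.83, PROM1 at -1.87 and -1.05, and CLDN6 at 1.60 in the TRα1 pool and 0.17 in the TRβ1 pool.

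Between the TRβ1 and TRα1 pools on vehicle, 0 features passed in limma without the block (unadjusted p under 0.05 for 593), and 111 passed with it, 60 higher and 51 lower in the TRβ1 pool. The count with the block fell to between 41 and 86 with any single array of these groups left out. The genes given here were chosen after their values were seen, with SE and adjusted p from the fit with the block. PAQR9 differed by 1.19 ± 0.10 (adjusted p = 1.4e-04), DOCK9 by 1.16 ± 0.17, SGK1 by 0.88 ± 0.11 and TTR, the carrier protein transthyretin, by 0.58 ± 0.08. Lower in the TRβ1 pool were CLDN6 at -1.43 ± 0.20, SLC2A2, the liver glucose transporter GLUT2, at -1.20 ± 0.13, FYN at -0.82 ± 0.10 and the complement genes SERPING1 (-0.99 ± 0.12) and C1S (-0.78 ± 0.09). Wnt target genes were lower (median -0.22, adjusted p = 7.8e-05; adjusted p = 0.941 with an estimated correlation), with 0 members called over all features and 2 adjusted over the list alone, the Wnt inhibitors APCDD1 and DKK1 (-0.55 ± 0.14). With the block this list had an adjusted p of 4.7e-07, and an adjusted p = 0.043 with an estimated correlation. Acute phase and complement genes passed with the block alone (median -0.18, adjusted p = 1.7e-05; adjusted p = 0.088 with the block and an estimated correlation).

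Of the 36 lists, 25 passed camera in none of the 9 contrasts, with 0.096 as their smallest adjusted p. Among markers of cell types, the lists for cholangiocytes and progenitors, fibroblasts and stellate cells, endothelium, blood cells and hepatocyte secreted proteins had smallest adjusted p of 0.147, 0.437, 0.173, 0.147 and 0.136, with PROM1, CD14 and ITIH4 as their called members without the block, and SPP1, LYZ, HPX, TTR and SERPINA3 added on vehicle with it. Genes for thyroid hormone receptors and coregulators, for hormone transport and metabolism, fatty acid oxidation, gluconeogenesis, glycolysis and the hypoxia response had 0.401, 0.486, 0.243, 0.304, 0.552 and 0.399. Single members of these lists were still called on T3 without the block. They included CPT1A of fatty acid oxidation in the TRα1 pool and PCK1 of gluconeogenesis in the TRβ1 pool. SLC2A1, in the glycolysis and hypoxia lists, was called lower in both receptor pools. Liver transcription factors, epithelial mesenchymal transition and matrix, and cell cycle and proliferation had 0.335, 0.410 and 0.556. The unfolded protein, heat shock and oxidative stress lists had 0.579, 0.578 and 0.578, and immediate early genes 0.096. The mitochondrial respiratory chain, mitochondrial biogenesis, ribosomal proteins, and amino acid and urea cycle lists had 0.556, 0.780, 0.335 and 0.494. Lipogenesis (0.147), apolipoproteins and lipid secretion (0.208), and cell cycle inhibitors and p53 targets (0.127) passed in at least 1 contrast with the block, at smallest adjusted p of 0.037, 0.020 and 0.020, and none of the 3 did with the block and an estimated correlation. With the block APOC1 stood among the apolipoproteins at 0.97 in the TRα1 pool on T3.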

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

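The tests of selection on the receptor arrays, of the shared control arrays, of the weaker control response with the replicate block, of single arrays by their weights, and of isoform differences with the replicate block were chosen only after the result was seen.

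The response to T3 differed between pools, by the test of the difference with the replicate block, for 6 genes between the TRα1 and control pools: CYP24A1 (1.46), ENG (1.41), KCNJ10 (1.38), PTAFR (1.37), FYN (1.15) and ZNF717 (1.01). None of them passed without the block. ZNF717 responded at 0.66 in the TRα1 pool and at -0.34 in the control pool. CYP24A1 rose in the TRα1 pool from a lower level on vehicle than in the control pool (-1.04). Between the TRβ1 and TRα1 pools, genes were tested over features called in either, a choice on the same arrays that favours such differences. There KCNJ10 passed at -0.83 with and without the block, and EXOC5 (-0.70), ETNPPL (-0.69) and ZNF717 (-0.47) passed with the block. Over all features 0 passed in either fit. Without the block the count of 1 ranged from 0 to 3 when single arrays were left out. With 1 pool of clones per construct, isoform and clones cannot be told apart. Outside the tested features, the 11775 features without a gene symbol held 7 that responded to T3 in the TRα1 pool with the block and 4 in the TRβ1 pool, against 0 in the control pool. Without the block the numbers were 1, 1 and 0. Array weights in limma were 0.393 to 0.573 for the arrays numbered 1 and 1.07 to 1.81 for the others, and with the block lay between 0.412 (control vehicle replicate 2) and 3.64 (TRα1 T3 replicate 3).

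The arrays numbered 1 stood apart from those numbered 2 and 3 in all 6 groups. A shift of dim features alone was argued against, as 77.0% of the 5137 brightest features (3957) differed between number 1 and the others, against 19.6% of the 5137 dimmest. A different state of the cells in culture is a candidate explanation: 3 of 36 gene lists differed with an estimated correlation, the respiratory chain (median 0.64), ribosomal proteins (0.42) and apolipoproteins (0.28), all higher in number 1. A difference in RNA or array handling was not tested and stays open, and the labels give no dates. No biological explanation from the design was tested, as each number holds all 6 groups.

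Genes called higher in the TRα1 pool responded less in the control pool than in the TRβ1 pool, with a median difference of 0.37 over 26 features, above 0 for all 26. Selection of these features on the TRα1 arrays was argued against, since the TRβ1 and control arrays took no part in it beyond the shared variance and the difference had p = 5.9e-05 by camera with an estimated correlation. A constant effect of the replicate number cancels in this difference by design, as each number holds all 6 groups, so testing it decides nothing. The medians within numbers 1, 2 and 3 were all above 0 (0.42, 0.46 and 0.199), so no single number carried the difference. The lowest median fell just short of the bound of 0.2 set before. By camera with the block and an estimated correlation the difference had p = 2.4e-05. Added receptor stays a candidate explanation, and so do differences between the pools of clones, of which each construct had 1.

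The TRα1 and TRβ1 pools differed from the control pool on vehicle in 17 of the same features, all in the same direction. The shared control arrays as the whole source were argued against, as on the T3 arrays, which took no part in the calls, the 17 differed from control in the direction called in both pools, with medians of 1.46 (TRα1) and 1.02 (TRβ1). Over all features the covariance of both differences was 0.0215 and their correlation 0.655, against 0.0078 and 0.499 in arrays simulated with shared controls alone and the block, and a covariance of 0.022 without the block, where the replicate effect adds to the simulated spread. Different clones in the pools may account for these differences as well as the receptors: the design holds 1 pool of clones per construct, so both explanations cannot be told apart.

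Regrouping the arrays into 3 against 3 gave 10 splits per comparison, so that no share under 0.1 can be reached. For T3 against vehicle in the TRα1, TRβ1 and control pools, the real split gave 27, 15 and 2 features and the highest other 0, and for the TRα1 and TRβ1 pools against control on vehicle 63 and 24 against 0, so 1 split of 10, the real one, gave as many. The 3 differences between responses and the TRβ1 minus TRα1 difference on vehicle had 0 features in the real split and in the others, so all 10 gave as many (limma; 286, 275, 223 and 593 features had an unadjusted p under 0.05). Among the 4 splits that part every same-numbered pair, with the block, the real split gave 137, 98, 20, 6, 0, 0, 425, 151 and 111 in the order of the contrasts, and the highest other gave 0 except 1 for the TRβ1 pool against control on vehicle.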

How the results depend on the processing

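The settings with the arrays numbered 2 and 3 alone, the gene list tests with the block, every alternative for the isoform differences, the overlap with a random block, centring, the trended prior, array weights and arrays left out, the medians of called features with arrays left out, and the counts with the block after leaving out arrays were chosen only after the result was seen. Counts of features are given for T3 in the TRα1, TRβ1 and control pools, for the differences of responses, and for the pools on vehicle. No named gene reversed under any setting run. The cause was not tested for any change except where fewer arrays or features were used.

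The replicate block as a fixed term moved the counts to 137, 98 and 20 for T3, 6 for TRα1 against control responses, and 425, 151 and 111 for TRα1 against control, TRβ1 against control and TRβ1 against TRα1 on vehicle, with an overlap of 85 and 4 isoform differences. As a random term it gave 121, 82, 17, 6, 292, 109, 84, 69 and 4. With only the arrays of the groups compared, which leaves fewer arrays to estimate the spread, the 3 T3 counts were 6, 0 and 0, and those of TRα1 and TRβ1 against control on vehicle 13 and 0. Array weights gave 41 and 5 for T3 in the TRα1 and control pools, 1 for TRα1 against control responses, and 95, 39 and 15 on vehicle. Renewed quantile normalization and median centring gave 2 and 1 for TRα1 against control responses. All features together gave 8 for T3 in the TRβ1 pool, and the arrays numbered 2 and 3 gave 4 there, an overlap of 4 and 2 isoform differences. An adjusted p under 0.01 left an overlap of 5. Omission of dim features, 1 feature per gene, the trended and robust prior and the 1.5-fold minimum kept every count within 1.5 times.

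With an estimated correlation and with fry in 1 direction, 0 lists passed in each of the 8 contrasts where camera had called any. Fry in either direction gave 3 for T3 in the TRβ1 pool, 0 in the control pool, 0 and 0 for both receptors against control responses, and 5, 1 and 0 on vehicle. Camera with the block gave 9 and 5 lists for T3 in the TRα1 and control pools and 2 and 2 for TRα1 against control and TRβ1 against TRα1 on vehicle. With the block and an estimated correlation it gave 1, 3 and 0 for T3, 0 and 0 for both receptors against control responses, and 0 and 0 for both against control on vehicle.

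Of 70 named results, 70 kept their call with the block, fixed or random, and with 1 feature per gene, 68 with array weights (PCK1 in the TRβ1 pool at adjusted p = 0.106 and CLDN6 did not) and with the 1.5-fold minimum, 67 with the trended prior, 63 with centring, 61 with quantile normalization, 50 with all features, 41 with numbers 2 and 3 and 16 with only the arrays compared. All 64 that were bright enough kept it without dim features. On vehicle, H2BC12 and CLDN6 in the TRα1 pool and CYP24A1, H2AC12, SLAIN1, MUC15 and CDCA7L in the TRβ1 pool lost the call with both quantile normalization and centring, in the same direction as before. Leaving out single arrays kept 255 of 420 calls.

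With each array left out in turn, T3 counts ranged from 12 to 24 (TRα1), 5 to 10 (TRβ1) and 2 to 3 (control), the differences of responses from 0 to 1 (TRα1 against control), 0 to 0 (TRβ1 against control) and 0 to 0 (TRβ1 against TRα1), and the vehicle counts from 29 to 45, 9 to 13 and 0 to 2, with an overlap of 5 to 12 and 0 to 3 isoform differences. The TRα1 count was 12 without T3 replicate 2 and 15 without vehicle replicate 3. The TRβ1 count was 5 without vehicle replicate 1, vehicle replicate 3 or T3 replicate 2 and 8 without T3 replicate 1. TRα1 against control responses had 1 without TRα1 T3 replicate 3 or control vehicle replicate 1. On vehicle, TRα1 against control fell to 29 to 37 without any array but control replicate 1 (45), TRβ1 against control to 9 to 13 without any array, and TRβ1 against TRα1 had 2 without TRα1 replicate 3. The overlap was 7 and 6 without TRα1 vehicle replicate 3 and T3 replicate 2, and 5, 9, 5, 8, 5 and 9 without TRβ1 vehicle replicates 1, 2 and 3 and T3 replicates 1, 2 and 3. The isoform count was 0 without TRα1 vehicle replicate 1 or T3 replicate 2 or TRβ1 replicates 2 or 3 of either treatment, 2 without TRα1 vehicle replicate 3 and 3 without TRα1 T3 replicate 3. The 26 features called in the TRα1 pool had medians of 0.43 to 0.50 in the control pool and -0.0753 to 0.0152 in TRβ1 against control on vehicle, where the lowest, without TRβ1 vehicle replicate 2, passed the threshold. The 14 called in the TRβ1 pool had 0.40 to 0.50 and -0.03 to 0.03.

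With the block, leaving out single arrays gave 89 to 99, 46 to 70 and 3 to 9 features for T3, 5 to 9, 0 to 2 and 0 to 1 for the differences of responses, and 203 to 299, 68 to 99 and 41 to 86 on vehicle. More than 1.5 times fewer were called without TRα1 T3 replicate 2 (89) or 3 (90), without TRβ1 vehicle replicate 1 (65) or 2 (56) or T3 replicate 1 (46) or 2 (65), without any control array for T3 in the control pool, without any vehicle replicate 2 or 3 of TRα1 against control, without any array of TRβ1 against control, and without any array but TRα1 replicate 1 of TRβ1 against TRα1. The difference of TRβ1 against TRα1 responses had 1 without TRα1 vehicle replicate 1, and TRβ1 against control had 2 without TRβ1 T3 replicate 3 and 1 without TRβ1 vehicle replicate 2 or control vehicle replicate 2. Fewer arrays left fewer degrees of freedom in each of these, which does not account for the counts that rose.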

Other observations

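The test of a common lowering of T3-raised genes was chosen only after the result was seen, and the genes of the next paragraph were chosen after their values were seen.

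On vehicle, SPINK1, a secreted trypsin inhibitor, was higher by 3.94 ± 0.36 (SE with the block) in the TRα1 pool and by 3.43 ± 0.36 in the TRβ1 pool than in the control pool, with adjusted p of 2.5e-05 and 1.5e-04 with the block and 0.274 and 0.783 without it. BAAT, which conjugates bile acids, was higher by 1.18 ± 0.11 in the TRβ1 pool (adjusted p = 7.4e-05 with the block, 0.308 without). HPX, the heme carrier hemopexin, was higher by 1.39 ± 0.18 in the TRα1 pool and by 0.96 ± 0.18 in the TRβ1 pool with the block, and at adjusted p of 0.163 and 1 without it. CDH1, the epithelial cadherin, was lower in the TRα1 pool at -0.81 ± 0.14, and AGR2 was lower in the TRβ1 pool at -1.14 ± 0.19, both with the block, and at adjusted p of 0.707 and 0.812 without it. On T3, OAS1, an interferon-induced enzyme, was lower at -0.49 ± 0.09 in the TRα1 pool and -0.48 ± 0.09 in the TRβ1 pool with the block, and at adjusted p of 0.313 and 0.472 without it. In the control pool OAS1 stood at -0.33, so the fall was not confined to the receptor pools.

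A hypothesis was that receptor without hormone lowers the genes that T3 raises. The 26 features called higher with T3 in the TRα1 pool had a median of -0.0145 in the TRβ1 minus control difference on vehicle, with quartiles of -0.124 and 0.0729, and the 14 called in the TRβ1 pool a median of -0.0117 in the TRα1 minus control difference. These values showed no common lowering relative to the control pool, though single genes went down, CYP24A1 at -1.68 in the TRβ1 pool. Without TRβ1 vehicle replicate 2, the median of the 26 was -0.0753 and passed camera at the preset correlation. The control pool itself responded to T3 in these genes, so a lowering present there as well would not be seen.

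A second hypothesis was that T3 raises genes that are lower in a receptor pool on vehicle, which was written before the test, although the values of CYP24A1 had been seen. The 47 features lower in the TRβ1 pool with the block had a median of -0.0024 in the T3 response of the TRα1 pool, where camera's direction was up (p = 0.0182; p = 0.211 with an estimated correlation; 0.375 without CYP24A1). The 141 features lower in the TRα1 pool had a median of -0.0354 in the T3 response of the TRβ1 pool (p = 0.368; p = 0.709 with an estimated correlation). The result was negative.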
